A study of Wyeomyia smithii with 24 samples.

How the data were processed

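Gene expression was measured in heads of adult female Wyeomyia smithii, the mosquito whose larvae live in the water held by pitcher plant leaves. The platform was a custom NimbleGen expression array for this species, on which each sample is read in 1 dye, Cy3 or Cy5. The series held 24 samples from 3 populations, with 8 samples per population. These were 4 biological replicates per population, each hybridised 2 times, once with each dye. WI stands for non-biting individuals of the base population, WIOB for biting individuals of a line derived from WI by selection for biting, and KC for a northern population that never bites. Groups followed the sample titles and source names. Other label fields did not fully match them: the strain field read WI for every sample, KC included, and the population field placed the WIOB biters in the base population.

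Per the labels' protocols, RNA was extracted with Trizol, purified on columns with DNase treatment, amplified, converted to double-stranded cDNA and labelled with random primers. The deposited files gave 1 intensity for each of 130866 probes per sample. The deposited intensities had been quantile-normalized by the authors over all samples with random probes included, per the labels' design text. The values were on a linear scale, and the median intensity per sample lay between 481.06 and 481.62. The software behind these steps is not given in the sources used here. The deposited values for the whole series held the same values as the sample files, with a largest difference of 0. Quantile normalization gives every sample the same distribution of intensities, so a shift of most transcripts in 1 direction in 1 population would not be seen.

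Because the intensities were already normalized, no background correction or further normalization was applied, although a correction had been planned for raw scanner values. The intensities were changed to log2 and averaged over the probes of a feature, and the 2 hybridisations of a biological replicate were then averaged. Of the 276 pairs of samples, 0 held identical values, and at most 0.0222% of probes were equal in any pair. A feature was a target sequence of the array. There were 67625 features, of which 21279 were contigs, assembled sequences, and 46346 carried other identifiers and were covered by 1 probe each. These are called single-probe features here. Most contigs (21000) had 4 probes, and 279 had 1 to 3. Every probe was 60 nucleotides long.

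The files did not pair features with genes, and 0 of the feature identifiers matched any of the 17568 genes listed for the assembly ASM2978416v1. The 23 gene lists fixed before the data were examined therefore had 0 members found and no result, and no genome position or annotation is given here for any feature. The rule for this case, also fixed before the data were examined, was to name for each comparison at most the 2 features with the largest rise and the 2 with the largest fall. They had to pass the test and show no overlap between the 4 values of one population and the 4 of the other.

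Features were tested where the mean log2 intensity lay above 6.472, the 20th percentile of all feature values, in at least 4 of the 12 biological replicates. This was the planned fallback, since no random probes were used here. It left 57682 features (20588 contigs and 37094 single-probe features) and removed 9943. The 3 populations were fitted in a single model with limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3, data.table version 1.17.8), with 9 residual degrees of freedom and a prior of 4.12. Each of the 3 comparisons was two-sided, with Benjamini-Hochberg adjustment over the features tested and a threshold of 0.05. All counts, changes, standard errors and adjusted p-values below come from this limma fit unless stated. Dye was balanced within each biological replicate and was not a term. Which samples shared an array is not given in the labels, so a shared array was not a block. A change is given on the log2 scale or as a fold of normalized intensity. No background was removed here, and whether it had been removed from the deposited values is not known. Any background left understates the true ratio for dim features.

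As a measure of how strongly the signal changed along contigs, the slope of log2 intensity with probe position was taken for each biological replicate. It used 9299 contigs with 4 probes spanning at least 500 nucleotides. The sign of each contig was set by the mean of the other replicates, so a larger slope means stronger trends along contigs. The slope does not tell which end of a transcript gave more signal. For a KC replicate most of the others are WI or WIOB replicates, which by itself can lower KC slopes. A position between populations was computed by projecting each replicate on the line from the WIOB mean (0) to the KC mean (1), leaving the replicate out of its own mean.

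The procedure was tested on simulated data with 57682 features and known changes, 50 features for each size of change. In WIOB against WI it recovered 2% of changes of 0.5 on the log2 scale, 46% of changes of 1, 94% of changes of 2 and 100% of changes of 3, with 7 false calls. In KC against WIOB the shares were 2%, 56%, 94% and 100% with 6 false calls. In KC against WI they were 0%, 72%, 94% and 98% with 12 false calls. Far more features were called in the real comparisons than were changed here, above all in those with KC. That loosens the Benjamini-Hochberg cut, so these shares do not give the recovery in the real data. The number of replicates, 4 per population, limits the precision, and the standard error of a change had a median of 0.195.

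Alternatives covered the scaling between samples, the filter on dim features, the summary of probes, the use of single hybridisations or of a single dye, a replicate block, the samples in the fit, the variance model, a minimum change, and leaving out each biological replicate. Alternatives chosen after seeing the data were an offset of 50 before log2, a filter at the 40th percentile, contigs with 4 probes only, the slope along contigs as a covariate, and leaving out WIOB 4 and KC 1 together.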

Results

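The design asked how head transcripts differ between mosquitoes that bite and mosquitoes that do not. Biters of a selected line (WIOB) were set against non-biters of their base population (WI), and both were set against a northern population that never bites (KC). All biters came from the selected line, so an effect of biting cannot be told apart from other differences between these populations. Each population was represented by 4 biological replicates, each the mean of 2 hybridisations of opposite dye. The labels name the replicates as biological without saying how many heads or cohorts stand behind them. Of the 67625 features on the array, 57682 were tested. Within a population the log2 intensity of a feature varied between replicates with a median SD of 0.282 (n = 4 per population). The 2 hybridisations of a replicate correlated across features at 0.982 to 0.991.

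The populations separated mainly along a single axis. The first principal component held 64.7% of the variance over the 12 biological replicates and set KC apart from the other two. Mean scores were 144.7 ± 37.4 (SD, n = 4) in KC, -49.8 ± 25.2 in WI and -95.0 ± 6.35 in WIOB. The second component held 11.3% and set WIOB replicate 4 apart, at -118.7. KC replicate 1 had a score of 91.7 on the first component, below the 153.5 to 179.4 of the other KC replicates. The median correlation across features was 0.969 between WIOB and WI replicates, 0.917 between KC and WI replicates and 0.883 between KC and WIOB replicates.

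**Figure D1:**
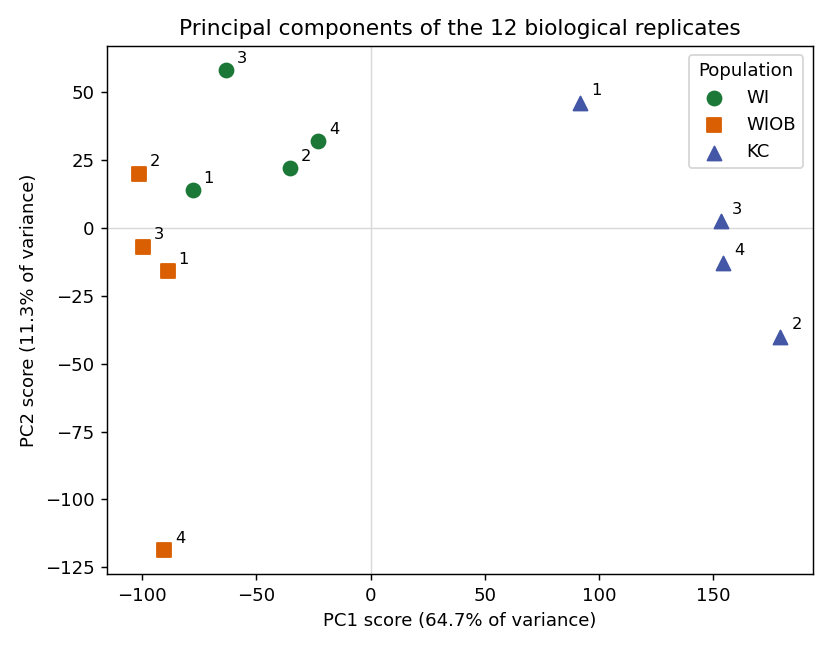
Scores of the 12 biological replicates on the first principal component (horizontal axis, 64.7% of variance) and the second (vertical axis, 11.3%). Each point is 1 biological replicate, numbered within its population. KC lies at 91.7 or above on the first component and WI and WIOB lie below 0, while WIOB 4 lies at -118.7 on the second.

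Biters of the selected line were compared first with non-biters of the population the line was derived from. Of the 57682 features tested, 1868 (3.24%) differed, with 740 higher and 1128 lower in WIOB. The feature with the largest rise, F5BTJ3O02GOJS2, had a log2 intensity of 13.52 ± 0.456 in WIOB and 8.34 ± 0.198 in WI (SD, n = 4 each). Its change was 5.18 (SE 0.211, limma adjusted p = 1.396e-07), a 36.2-fold difference, and its mean in KC was 7.55. F5BTJ3O01EKOXI was higher in WIOB by 3.11 (SE 0.215, adjusted p = 3.743e-05), and its mean of 10.12 in WI lay above the 7.55 in KC. CONTIG18048 had the largest fall, at 8.83 ± 0.687 in WIOB against 13.44 ± 0.636 in WI. Its change was -4.60 (SE 0.384, adjusted p = 0.0001492), and its 4 probes changed by -4.03 to -4.95. F5BTJ3O01AYQMN changed by -4.33 (SE 0.393, adjusted p = 0.0001908). In KC the means of CONTIG18048 and F5BTJ3O01AYQMN were 12.90 and 14.56, and their differences from WI did not pass the test (adjusted p = 0.275 and 0.892).

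The features that changed at least 4-fold between WIOB and WI were mostly lower in the biters. Among called features, 305 were higher and 596 lower by at least 2-fold, and 14 were higher and 113 lower by at least 4-fold. In the brightest of 4 equal classes of intensity 99 were higher and 370 lower. Contigs and single-probe features were called at like rates, 3.12% (642) and 3.31% (1226). No feature was dim, below 6.472, in all 4 replicates of one of these populations and bright, above 8.472, in all 4 of the other. The 4 values of one population lay entirely on one side of the other's for 7606 features, 13.2% of those tested, where chance gives 2.86%. The excess of lower calls over all called features turned without WIOB replicate 4, with 670 higher and 565 lower. Without it lower calls were still the more numerous at 2-fold or more (318 higher and 365 lower), at 4-fold or more (22 and 100) and in the brightest class (33 and 169). The excess in the brightest class turned without KC 1, with 554 higher and 543 lower, while 460 were higher and 707 lower at 2-fold or more, and the count was then 3430. Without WIOB 4 and KC 1 together, 182 were higher and 305 lower in the brightest class, 480 and 501 at 2-fold or more, and 23 and 101 at 4-fold or more. It was 3147 without WI 1, 748 without WI 2, 819 without WI 3, 661 without WI 4, 1012 without WIOB 2, 616 without WIOB 3, 1235 without WIOB 4 and 983 without KC 4. A fit of WI and WIOB alone called 1061.

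**Figure D2:**
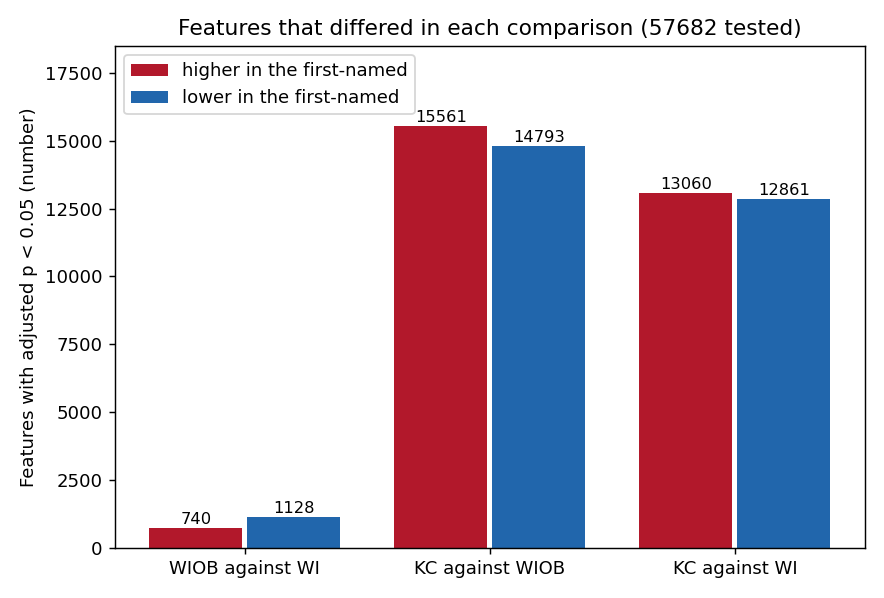
Number of features with a limma adjusted p under 0.05 (vertical axis) in each of the 3 comparisons, out of 57682 tested. Red bars count features higher in the first-named population and blue bars those lower, from 740 and 1128 for WIOB against WI to 15561 and 14793 for KC against WIOB.

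The obligate non-biters were next compared with the biters of the selected line. KC differed from WIOB in 30354 features (52.6%), with 15561 higher and 14793 lower in KC. F5BTJ3O02F09V3 was higher in KC by 5.87 (SE 0.328, limma adjusted p = 2.886e-08), a 58.3-fold difference, with 12.84 ± 0.129 in KC and 6.97 ± 0.236 in WIOB (SD, n = 4 each). F5BTJ3O01ENUCY was higher by 5.82 (SE 0.215, adjusted p = 1.57e-09). F5BTJ3O02FZAPZ had the largest fall, -6.46 (SE 0.866, adjusted p = 4.618e-05), from 13.82 ± 1.06 in WIOB to 7.37 ± 0.447 in KC. F5BTJ3O02ILM5J changed by -6.13 (SE 0.377, adjusted p = 6.175e-08). In WI these 4 features had means of 8.77, 10.37, 12.56 and 11.75, each between the other 2 populations. The WI values of F5BTJ3O02FZAPZ ranged widely, with an SD of 2.27. WI 2 was the lowest at 9.44, and the difference between WIOB and WI did not pass the test (adjusted p = 0.443).

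The difference between KC and WIOB was spread over the whole intensity range and over both kinds of feature. By at least 2-fold, 7672 features were higher and 7220 lower in KC, and by at least 4-fold 1413 were higher and 1870 lower. The share called rose with brightness, from 33.1% in the dimmest intensity class to 66.2% in the brightest. It was 58.6% (12065) of contigs and 49.3% (18289) of single-probe features. Between these populations 39 features were dim in all WIOB replicates and bright in all KC replicates, and 14 the other way. The values of the populations did not overlap for 26160 features (45.4%, where chance gives 2.86%). Among the contigs with 4 probes that were called (11925), 87.7% had all 4 probes changed in one direction, against 36.5% of those not called. Independent probes would give 12.5% by chance, but probes of a contig measure the same sequence and can overlap. Because calls rest on the mean of these 4 probes, called contigs are favoured to agree.

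The comparison of KC with the base population set the obligate non-biters against non-biters of the population from which the biting line was selected. KC differed from WI in 25921 features (44.9%), with 13060 higher and 12861 lower in KC. CONTIG12280 had the largest fall, -5.73 (SE 0.152, limma adjusted p = 5.232e-10), from 13.39 ± 0.180 in WI to 7.66 ± 0.261 in KC (SD, n = 4 each). Its 4 probes changed by -5.62 to -5.82, and its mean in WIOB was 13.59. F5BTJ3O01CBIHW changed by -5.51 (SE 0.226, adjusted p = 8.133e-09). F5BTJ3O02FUID2 was higher in KC by 4.66 (SE 0.212, adjusted p = 1.45e-08), a 25.2-fold difference, and F5BTJ3O02H3YBL by 4.36 (SE 0.304, adjusted p = 2.981e-07). All 4 of these features had WIOB means within 1 log2 unit of the WI means. At least 2-fold differences were found for 5852 features higher and 5633 lower, and at least 4-fold differences for 805 and 955. The share called was 51.3% (10570) of contigs and 41.4% (15351) of single-probe features. The values did not overlap for 23102 features (40.1%, where chance gives 2.86%). Leaving out KC 1 and WIOB 4 together gave 29973 features for KC against WI and 32735 for KC against WIOB.

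**Figure D3:**
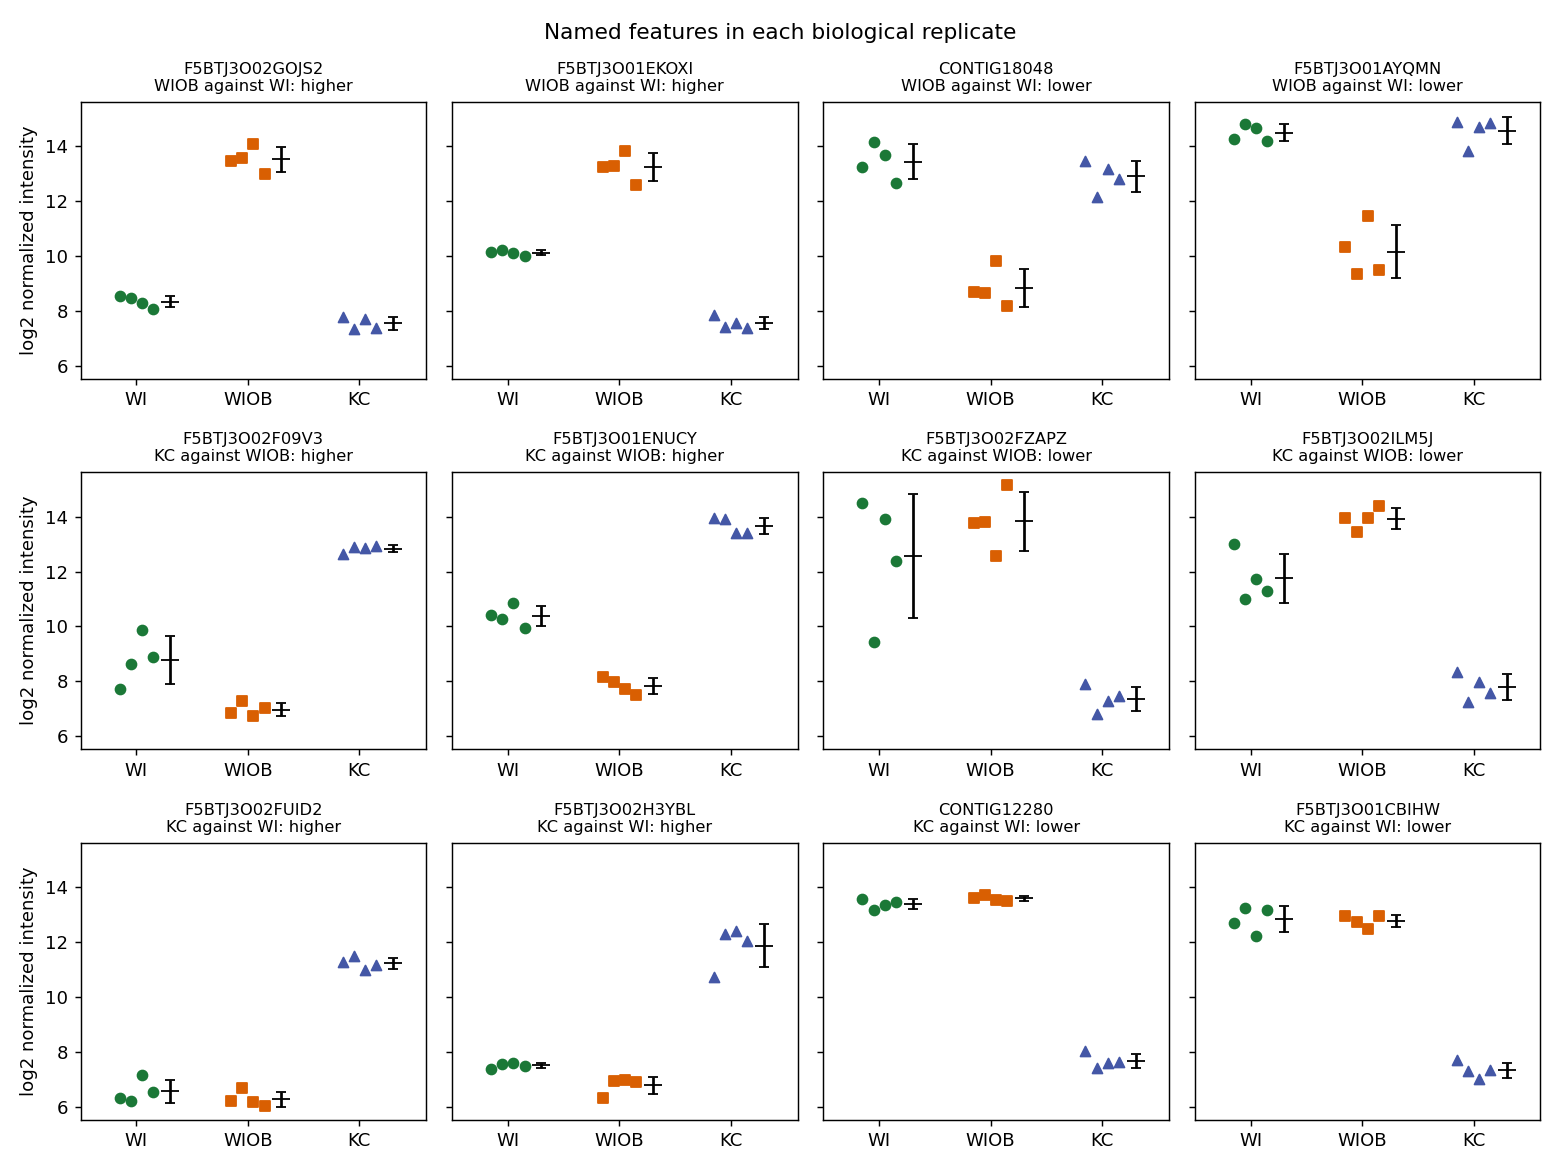
Log2 normalized intensity (vertical axis) of the 12 named features in WI (green circles), WIOB (orange squares) and KC (blue triangles). Each point is 1 biological replicate, and the black bar beside each population shows the mean ± SD (n = 4). CONTIG18048 lies at 8.83 on average in WIOB and above 12 in every WI and KC replicate, while CONTIG12280 lies at 7.66 in KC and above 13 in every WI and WIOB replicate.

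Features that set the biters apart from both non-biting populations were counted from the first 2 comparisons. WIOB was the only biting population, so these features may mark the selected line rather than biting. In WIOB 683 features were higher than in both WI and KC, 92.3% of the 740 higher than in WI, and 744 were lower than in both, 66.0% of the 1128. F5BTJ3O02GOJS2 and F5BTJ3O01EKOXI were among the former, and CONTIG18048 and F5BTJ3O01AYQMN among the latter. Of the 683, 407 were also higher in WI than in KC, and of the 744, 330 were also lower in WI than in KC. In these features the 2 non-biting populations differed as well, with WI between WIOB and KC. Independent lists of the same lengths would share 189.8 and 304.3. Both comparisons use the same WIOB replicates, which raises the overlap by itself. In 20 simulations without any effect 0 features were shared, but few features are called without an effect, so this value does not give the overlap that the shared replicates add to lists of these lengths. With the WIOB replicates split so that each comparison used a different pair, the 6 splits gave 102 to 258 features higher in WIOB, 3.31 to 4.15 times the number for independent lists. They gave 149 to 329 lower, 2.50 to 3.62 times that number. The balance of the 2 directions was not stable and turned in 8 of 26 alternatives. Among these were leaving out WIOB 4, with 629 higher and 382 lower, KC 1, with 1520 and 1199, and both, with 1404 and 738, and also settings that kept all 12 replicates. The total of 1427 moved to 2719 without KC 1, 2452 without WI 1, 572 without WI 2, 664 without WI 3, 509 without WI 4, 766 without WIOB 2, 487 without WIOB 3 and 758 without KC 4. Features that set KC apart from both other populations were more numerous, with 11577 higher and 10524 lower in KC than in either. At least 1 comparison called 34196 features (59.3%), and 23486 were called in none.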

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

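The tests of a mislabelled KC 1 and of a single faulty hybridisation of WIOB 4 were chosen after their results were seen, as was the bound used in the second test of a mixed KC 1. Of 54 groups of 4 replicates searched for a value far from the other 3, 1 was found, where about 2.7 would be found by chance. F5BTJ3O02H3YBL lay at 6.32 in WIOB 1 and at 6.89 to 6.98 in the other WIOB replicates. No explanation was tested for it.

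KC replicate 1 lay toward WI and WIOB, at 0.664 of the way from them (0) to the other KC replicates (1) and above every WI and WIOB replicate, which argues against a WI or WIOB sample under a KC label. If RNA of WI or WIOB had been mixed in, features high in those populations would rise, and 79.6% of 54 such features exceeded KC 2 to 4, with an implied share of 0.270% to 5.76% (10th to 90th percentile). That share allows a change of -0.0855 in features high in KC, while 1006 features at least 4-fold higher in KC 2 to 4 had a median change of -0.800 (quartiles -1.49 and 0.0136), which argues against mixing as the whole cause, although the bound set beforehand, 0.5 further down on 12 features at least 16-fold higher in KC, was not passed at -0.538. A gradient in the signal along contigs cannot be told apart from other causes. The slope of 2.07 log2 per kb lay within the range of the 11 others. That range is a poor yardstick because KC 2 to 4 lay at 1.61 to 1.76. The signs of contigs for KC replicates also came mostly from WI and WIOB. The effect of slope in WI and WIOB correlated with the departure of KC 1 across features at 0.471. This lay between the values set for and against. A difference between cohorts of KC stays open and was not tested.

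WIOB replicate 4 stood apart from WIOB 1 to 3, with 502 features raised at least 4-fold and 4 lowered, against 16 to 145 raised in the 11 other replicates. Of the 502 raised, 99.8% exceeded the means of both WI and KC, a level that RNA mixed in at either population's mean would not reach. Single WI or KC replicates, which can lie above their mean, were not compared. Its 2 hybridisations departed together, with a correlation across features of 0.838, which argues against a single faulty hybridisation. A gradient along contigs cannot be told apart from other causes. The slope of WIOB 4, 1.94, lay within the range of the 11 other replicates but below the 2.04 to 2.26 of WIOB 1 to 3. The effect of slope in WI and KC correlated with the departure of WIOB 4 at -0.285, between the values set for and against. A difference between cohorts of the selected line stays open and was not tested.

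KC differed from both other populations in a large share of features, and the population whose sequences the probes were designed on is not given in the sources used here. The agreement of probes in KC against WIOB argues against sequence differences under only 1 of the 4 probes as the source of most calls. All 4 probes changed in one direction in 87.7% of called contigs and in 36.5% of those not called. Calls used the mean of the same 4 probes, which itself favours agreement. Probes of a contig can also overlap, as the 60-nucleotide probes of CONTIG12280 at positions 162, 173 and 183 did. A sequence difference shared by overlapping probes can change several of them together, and the agreement does not argue against that. How many contigs have overlapping probes was not counted. The share among called contigs was higher in KC against WI, at 92.0%, and in WIOB against WI, at 97.8%. Among single probes, 591 fell and 479 rose by at least 1.5 log2 relative to their contig in KC against WIOB, a ratio of 1.23, against 1.14 in WIOB against WI. In KC against WI 307 fell and 296 rose, a ratio of 1.04, while in WIOB against WI 24 fell and 21 rose. The ratio named in advance, that of KC against WIOB, lay between the values set for and against. Without knowing which population the probes came from, the ratios do not decide whether sequence differences underlie the deviating probes. Single-probe features have no other probe to compare with. Divergence in expression between the northern and the base population stays among the open explanations, untested. So do sequence differences spread over whole contigs or shared by overlapping probes.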

How the results depend on the processing

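Alternatives chosen after seeing the data were the offset, the filter at the 40th percentile, contigs with 4 probes only, the slope covariate, and leaving out WIOB 4 and KC 1 together. The 12 named features kept their direction and stayed past the threshold in all 326 alternative results, with adjusted p at most 0.002702. The counts for KC were within 1.5 times of the reported 30354 and 25921 in 26 of 28 alternatives each, the exceptions being a minimum change of 1 on the log2 scale (14892 and 11485) and contigs with 4 probes only (12255 and 10881), both of which count fewer features by construction. The count for WIOB against WI (1868) was within 1.5 times in 13 of 28. It was 3838 with 24 single hybridisations, a fit with a dye term and a random effect of the biological replicate. The count was 1039 with Cy5 only, 1061 with the 2 populations alone and 901 with a minimum change of 1. With contigs of 4 probes it was 646, and with the slope covariate 5978. The 1427 features that set WIOB apart became 2888 with 24 single hybridisations, 793 with Cy5 only, 489 with contigs of 4 probes, 3930 with the slope covariate and 2142 without WIOB 4 and KC 1. With the 2 populations alone the changes stay the same, and only the estimate of the spread and its degrees of freedom differ. Leaving out a KC replicate likewise acts on WIOB against WI only through the spread and the filter on features. For the other settings, except those that count fewer features, the cause was not tested. Leaving out 1 replicate gave 616 (without WIOB 3) to 3430 (without KC 1) features for WIOB against WI and 487 (without WIOB 3) to 2719 (without KC 1) for those that set WIOB apart. The share of WIOB against WI calls that were higher was 39.6%, and it was 54.2% without WIOB 4, 58.3% without WIOB 4 and KC 1, 49.7% with the slope covariate, 28.5% without WI 2 and 29.5% without WI 4. Whether the replicate numbers pair the samples is undecided. The labels do not say so and 6 of 12 same-numbered pairs correlated above 0.1, short of all of them, while 7 of 12 replicates matched their own number best and the mean correlation was 0.0739 for equal numbers and -0.0259 for others. With the replicate number as a block the counts were 1337, 30005, 25454 and 1056. Of the 1427 features, 683 were higher and 744 lower in WIOB, and this balance turned in 8 of 26 alternatives. With all 12 replicates it turned with the replicate block (555 higher, 501 lower), 24 single hybridisations (1634, 1254), Cy3 only (490, 465), the slope covariate (2224, 1706) and an offset of 50 (694, 674). Not run were the settings that need random probes, blocks for array, slide or scan (the files do not show them), the series table (identical) and the gene lists (no members). Scaling to one median moves almost nothing after quantile normalization and says little about stability. In WIOB against WI 1.16% of features were called in the dimmest of 4 equal intensity classes, 4.30% and 4.24% in the next ones and 3.25% in the brightest, and whether signal over background limits the calls was not tested.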

Other observations

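Tests of the slope along contigs were chosen after seeing the data. Of the 852 features that differed between all 3 pairs of populations, 737 had WI in the middle, 79 had WIOB and 36 had KC. Intensity rose from WIOB through WI to KC in 330 features and fell in that order in 407, while 6 rose and 73 fell from WI through WIOB to KC. With KC in the middle, 6 rose and 30 fell from WI to WIOB. Without WIOB 4, WI was in the middle of 198 rising and 367 falling features, WIOB of 5 and 42, and KC of 38 in all. Without KC 1 these numbers were 599 and 1099, 22 and 120, and 38. No other replicate was left out alone for these numbers. The features F5BTJ3O02F09V3, F5BTJ3O01ENUCY and F5BTJ3O02ILM5J, with WI means of 8.77, 10.37 and 11.75, show this order. On the line from the WIOB mean (0) to the KC mean (1), WI replicates lay at 0.231 ± 0.0987 (SD, n = 4) and WIOB replicates at 0.0450 ± 0.0292. The difference of 0.186 had a two-sided permutation p = 0.02857, the smallest that 4 against 4 allows. The line rests on the WIOB replicates and was not rebuilt for each regrouping. This permutation p is therefore not exact and does not decide whether WI lies nearer to KC. After Benjamini-Hochberg adjustment over 4 comparisons this permutation p was 0.1143. All 4 WI replicates lay above all 4 WIOB replicates on this line. The line starts at the WIOB mean, so a change in WIOB alone also places WI toward KC. On a line starting midway between the WI and WIOB means, the populations overlapped. There WI 1 lay at -0.0206, below WIOB 4 at -0.0160, and the other WI replicates lay above every WIOB replicate.

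The slope of intensity along contigs was 2.07 ± 0.130 log2 per kb in WI, 2.08 ± 0.134 in WIOB and 1.79 ± 0.196 in KC (SD, n = 4 each). The differences of KC from WI and from WIOB did not pass the test (exact two-sided permutation p = 0.08571 each, adjusted 0.1143). The signs of contigs for a KC replicate came mostly from WI and WIOB, which by itself can lower KC slopes. With the slope as a covariate, all 1868 features of WIOB against WI were still called among 5978. Of 100 assignments of the slopes within populations, the measured one included, 1 called as many, and the highest of the 99 shuffled ones was 5063 with a median of 1600. For KC the measured slopes did not stand out: the covariate lowered the counts to 23331 against WIOB and 18176 against WI, and 36 and 39 of the 100 assignments called as many. A candidate explanation for the 5978 is that a gradient related to the slope adds spread. This remains a hypothesis, since the covariate was chosen on these data. The counts for KC cannot decide it, because KC slopes were lower on average and the covariate takes up part of the KC difference. Shuffled slopes lowered these counts too, to medians of 21936 against WIOB and 16490 against WI.

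Regrouping the replicates bears on whether the counts could arise by chance. For WIOB against WI, 1 of the 35 splits of the 8 replicates gave as many calls as the real one (1868), which was the real split itself, and the highest of the others was 0. For KC against WIOB it was 1 of 35 (30354, highest other 6789), and for KC against WI 1 of 35 (25921, highest other 7300). The highest other splits grouped KC 1 with WIOB 1 to 3 and with WI 1 to 3. In each comparison the real split called the most, the strongest result that 35 splits allow. The other splits mix populations, which adds spread within groups and lowers their counts. They do not show how many of the calls are false. Of 100 regroupings of the 12 replicates, 3 gave at least as many features setting 1 group apart as the real 1427, and the highest other was 22063. That one put all KC replicates in the place of WIOB, and the next, at 8472, put 3 KC replicates there, so both reflect the separation of KC, a structure of the samples.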
